A study of Mus musculus with 48 samples.

How the data were processed

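Per the labels, whole blood was drawn by cardiac puncture from male C57BL/6 mice 24 h after the start of X-irradiation. Doses of 1.1, 2.2 and 4.4 Gy were given acutely at 0.85 Gy/min or at a low dose rate of 0.0028 Gy/min, and each rate had its own sham-irradiated group. Per the labels' protocols, blood was kept in PAXgene tubes, globin transcripts were depleted with GLOBINclear, and RNA was labelled with Cy3 for Agilent 1-colour arrays of the mouse genome. No pooling of mice is stated.

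The deposited spot intensity is the processed signal, a background-subtracted and spatially detrended brightness on a linear scale, per the file headers. It was made with Agilent Feature Extraction 10.7, and spots that did not rise above background carry a small positive surrogate. The deposited raw spot and local background intensity values were used for 1 alternative. The deposited series table holds log2 values, and a check against the arrays showed that they are the log2 processed signal shifted by 1 constant per array, with dim spots left blank. The deposited spot flags mark control spots, outliers and spots well above background.

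Groups were taken from the source names. The titles give the same group for the 36 exposed samples but no rate for the 12 sham samples, so the split of the sham samples by rate rests on the source names alone. The treatment tags and descriptions give another group for most samples, and the grouping by these tags was run as an alternative. For 48 of 48 samples the tags equal the source-name groups listed in a text order of the array file names, an order found after the labels had been compared, so the groups by tag mix the groups used here. The time needed for each exposure was computed from the stated dose and rate.

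The analysis started from the log2 processed signal, from which the 75th percentile of the non-control probes of that array was subtracted. Control and outlier spots were left out and the spots of 1 probe were averaged. A probe was kept when it was well above background on at least 6 of the 48 arrays and had at least 4 values in every group. Of the 39429 non-control probes, 31214 carried a name found in the RefSeq gene table and 26761 were named through an accession number in it. Of the 26559 probes kept, the one with the highest mean over all arrays stood for its gene, which left 20951 genes, of which 5865 carry a clone, model or accession number as their name. Probe positions are those of the array design on build mm9.

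Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 8 groups and all 48 arrays sharing 1 estimate of the spread. The fits gave the 6 exposed groups against their sham group, the difference between the rates at each dose, the sham groups against each other, the slope on dose within each rate, and the difference between the slopes. A dose-rate difference is the low-rate change minus the acute change, each against its own sham group. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. Changes are log2 differences with their standard error (SE).

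Gene lists were tested with camera at its preset correlation of 0.01 and with an estimated correlation, and with fry, all 3 from limma. The 27 lists cover p53 targets, blood cell types, repair, stress and metabolism. Adjustment was over the lists of a comparison, and a count adjusted over the list alone uses the p-values of its members only. Another 6 lists, of hepatocyte, acute-phase, pancreatic acinar, macrophage, mast cell and cardiac muscle genes, were written after the arrays had been examined, and their mean per array was compared with exact two-sided permutation tests. Correlations across arrays used deviations from the group mean, with 1e+05 permutations and 1e-05 as the smallest p that these can give.

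The groups, the tests, the 27 lists and the rule for named genes were chosen before the data were examined. Per comparison with sham, the rule takes called genes whose 6 exposed arrays all lie on 1 side of the sham mean. It names the 6 with the largest and the 6 with the smallest log2 change, passing over clone and accession names. It adds, from each of 10 lists, the 2 members with the smallest p. For the dose-rate, slope and sham comparisons it names the 5 largest and 5 smallest called effects and the same list members. The text gives a selection of the genes so named.

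The test was tried on simulated values for acute 4.4 Gy against acute sham, with 20951 genes and 6 arrays per group. With 100 genes changed 2-fold and 100 4-fold, 11 and 60 were recovered. The 72 calls held 1 false one and 0 in the wrong direction. A comparison without changes gave 0 calls. The 1 shifted list had an adjusted p of 1.21e-27 and 0 others were called. This does not test the preset correlation in real lists.

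The arrays lie on 12 slides and were scanned on 3 days. Alternatives fixed together with the tests were quantile normalization, normexp background correction, no filter on dim probes, a filter on all 48 arrays, outlier spots kept, the series table values and every probe tested. Also fixed then were a trended robust fit, a fit on the compared groups only, slide as a random or a fixed block, replicate number as a block, array weights, pooled sham groups, a comparison of the rates without the sham groups, groups by treatment tag, and each array left out in turn. Added after the data were examined were scan day as a block, comparisons within a scan day, a block for slides 5 to 8, leaving out 5 noisy arrays, the hepatocyte list mean as a covariate and the array's signal level as a covariate. For every comparison, 100 splits of the same arrays were also tested, the real one included. Depth here means signal over background, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.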

Results

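Gene expression in whole blood of male C57BL/6 mice was measured on 48 one-colour arrays. The mice were irradiated with X-rays, acutely at 0.85 Gy/min or at a low dose rate of 0.0028 Gy/min, or were sham-irradiated, and the doses were 4.4, 2.2 and 1.1 Gy. Each of the 8 groups held 6 arrays. Groups follow the source names, on which alone the split of the 12 sham arrays by rate rests, and with which the treatment tags are in conflict for 35 of 48 samples. Grouped by the tags instead, 0 to 3 genes passed in each comparison with sham. As described above, groups by tag mix those used here. The design asks how the blood response depends on the dose and on the rate at which the same dose is delivered. All blood was drawn 24 h after the start of irradiation. At the stated rates the acute doses took 1.29, 2.59 and 5.18 min. The low-rate doses took 6.55 and 13.1 h for the lower doses and 26.2 h for 4.4 Gy, so that 4.03 Gy would have been given by 24 h. Time since the end of exposure therefore differed between the rates along with the rate itself.

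Between 29.6% and 66.7% of the non-control spots of an array were well above background, and no spot was saturated. The group means of this share ran from 46.7% in acute sham to 60.5% in acute 4.4 Gy. The 75th percentile of the signal ran from 84.9 to 518 between arrays. The variation between repeated probes was 25.8% to 34.9% on the 4 arrays of slide 4 (2 of acute sham and 2 of acute 1.1 Gy, with 29.6% to 35.5% of spots well above background), and at most 15.0% on the others. The correlation across genes between arrays of 1 group had a median of 0.933, against 0.923 for arrays of different groups; genes are not independent replicates. Scan days were shared unevenly. Acute sham and low-rate sham had 3 arrays each on day 1 and on day 2, while all arrays of acute 2.2 and 4.4 Gy were scanned on day 3, on slides that hold no sham array. For those doses no comparison within a day exists, and values with scan day as a block rest on the other groups. Those with slides 5 to 8 as a block rest on acute 1.1 Gy alone (4 arrays on slide 5 and 2 on noisy slide 4). Relative to the 75th percentile, the median over all 20951 genes moved by -0.11 to -0.18 (log2) in the exposed groups, and by 0.11 in low-rate 4.4 Gy, and the changes given here include that shift.

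Transcripts of other tissues were present in varying amounts. The lists of these tissues were written after the arrays had been examined. The mean of 30 hepatocyte genes spread over 10.4 log2 units among the 12 sham arrays. It was higher than in acute sham by 2.94, 3.05 and 3.28 (log2) at acute 1.1, 2.2 and 4.4 Gy, with exact permutation p of 0.130, 0.0346 and 0.0476. At low-rate 1.1, 2.2 and 4.4 Gy the differences from low-rate sham were 2.31, 0.99 and 0.74, with exact permutation p of 0.0541, 0.535 and 0.582. None of the 6 passed adjustment over the family of 36 tests, where the lowest adjusted p was 0.132. The mean of 15 acute-phase genes, liver proteins of inflammation, was higher at acute 2.2 and 4.4 Gy by 3.96 and 4.29. Its exact permutation p was 0.00216 at both doses (adjusted p = 0.0195), with 6 of 6 exposed arrays above the highest sham array. At acute 4.4 Gy it was higher by 1.43 ± 0.29 (log2, SE) with the hepatocyte mean as a covariate, by 4.84 ± 1.78 with scan day as a block and by 4.29 ± 2.20 with slides 5 to 8 as a block. The mean of 22 macrophage genes was higher by 1.97 at acute 2.2 Gy (exact permutation p = 0.00433, adjusted p = 0.0312), by 2.52 at acute 4.4 Gy and by 3.06 at low-rate 2.2 Gy (exact permutation p = 0.00216, adjusted p = 0.0195 for both).

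**Figure D1:**
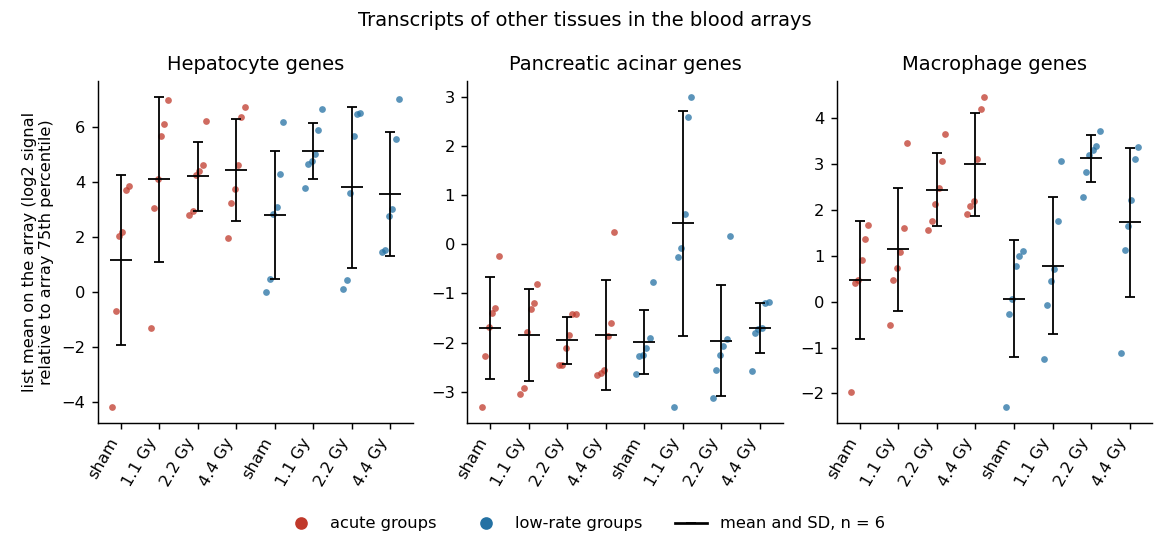
Mean log2 signal of the hepatocyte, pancreatic acinar and macrophage lists (y axis, relative to the 75th percentile of the array) in each of the 48 arrays, by group (x axis). Points are arrays and bars are the group mean with its SD; the hepatocyte mean ran from -4.19 to 7.0.

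Acute exposure to 1.1 Gy against acute sham asks what the lowest acute dose did. Cdkn1a, the cell cycle inhibitor p21 and a classical p53 target, rose by 2.37 ± 0.40 (log2, SE, 6 against 6 arrays, adjusted p = 0.00279). Fitted on the arrays of these 2 groups alone, 0 genes passed, and the 4 genes named for this dose had an adjusted p of 0.372 each. Aen, a p53-induced nuclease, rose by 1.56 ± 0.28 (adjusted p = 0.00557). Of 42 measured p53 targets 5 rose and 0 fell, or 13 and 1 adjusted over the list alone. Of 28 B-cell genes 7 fell and 0 rose, or 18 and 0 adjusted over the list alone. Among them was Cd79a, a part of the B-cell receptor, at -1.73 ± 0.39 (adjusted p = 0.0211). Of 40 erythroid genes 6 fell, or 24 adjusted over the list alone. Nusap1, which acts at the mitotic spindle, changed by -2.74 ± 0.57 (adjusted p = 0.0189). Of these 4 genes 3 lay beyond every sham array in 6 of 6 exposed arrays.

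The median changes at acute 1.1 Gy were 0.43 for p53 targets, -1.23 for B-cell genes and -1.31 for erythroid genes. Camera gave adjusted p of 5.67e-07, 4.06e-13 and 1.70e-13, and adjusted p = 0.152, 0.164 and 0.241 with an estimated correlation. Blocked by scan day, the medians were 0.41, -1.40 and -1.14, and within scan day 2 (2 exposed and 3 sham arrays) they were 0.58, -1.72 and -0.31. With the hepatocyte mean as a covariate they were 0.52, -0.86 and -0.94. Restricted to probes above background on all 48 arrays, the p53 median was -0.01. Taking slides 5 to 8 as a block, the erythroid median was -0.41 and its call ended (adjusted p = 0.115), as it did within scan day 2 (adjusted p = 0.416). In all, 207 genes passed, 36 higher and 171 lower, but 13 higher and 5 lower with the hepatocyte covariate. Left out in turn, each of the 12 arrays moved this count by over 1.5 times. It was 13 without exposed replicate 5 or sham replicate 6, 14, 31 and 103 without exposed replicates 4, 2 and 1, and 60, 94 and 93 without sham replicates 4, 5 and 2. It was 781 and 812 without exposed replicates 6 and 3, and 490 and 349 without sham replicates 1 and 3. The calls of Cd79a and Nusap1 ended without exposed replicate 4 (adjusted p = 0.0691 for both), exposed replicate 5 (0.102 and 0.0714) or sham replicate 6 (0.0780 and 0.0649). That of Cd79a also ended without exposed replicate 1 (0.0544) or sham replicate 5 (0.0531), and that of Nusap1 without exposed replicate 2 (0.0567). Under a block for scan day, 36 genes passed, and Aen, Cd79a and Nusap1 had adjusted p of 0.0573, 0.0769 and 0.127. Under normexp background correction 10 genes passed, and Cdkn1a was higher by 0.58 (adjusted p = 0.606). Within scan day 2, where 4 of the 5 arrays are those of slide 4, Cdkn1a was higher by 1.81 ± 0.59 (adjusted p = 0.130) and the calls of Aen, Cd79a and Nusap1 ended too (adjusted p = 0.317, 0.0891 and 0.678). A fixed block for slide ended all 4 gene calls, with Cdkn1a at 2.15 (adjusted p = 0.176), Aen at 1.37 (0.243), Cd79a at -2.17 (0.169) and Nusap1 at -1.0 (0.802), and the erythroid call (adjusted p = 0.239). The block for slides 5 to 8 ended those of Aen (1.14, adjusted p = 0.126) and Nusap1 (-1.50, adjusted p = 0.334).

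Acute 2.2 Gy against acute sham showed a wider response. Cdkn1a rose by 3.63 ± 0.40 (log2, SE, 6 against 6 arrays, adjusted p = 2.18e-07), and Phlda3, a p53 target that restrains Akt signalling, rose by 2.38 ± 0.31 (adjusted p = 6.58e-06). Of 42 p53 targets 9 rose and 1 fell, or 15 and 2 adjusted over the list alone. Of 28 B-cell genes 19 fell and 0 rose, or 21 and 0 adjusted over the list alone. They included Fcrl1 at -3.54 ± 0.44 (adjusted p = 2.77e-06), but -0.91 with normexp background correction (adjusted p = 0.325), and Fcmr, the IgM receptor, at -2.59 ± 0.41 (adjusted p = 7.89e-05). Of 26 platelet genes 8 rose and 0 fell, or 16 and 0 adjusted over the list alone. Tubb1, the platelet tubulin, was higher by 2.31 ± 0.36 (adjusted p = 6.62e-05) and Gp1bb, part of the von Willebrand factor receptor, by 1.91 ± 0.39 (adjusted p = 0.00143).

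Erythroid genes at acute 2.2 Gy went both ways, with 14 of 40 lower and 2 higher, or 25 and 2 adjusted over the list alone. Nusap1 fell by 2.93 ± 0.57 on the log2 scale (adjusted p = 0.000937), but by 1.07 ± 0.98 with slides 5 to 8 as a block (adjusted p = 0.570), where the call of Gp1bb ended too (1.84 ± 0.70, adjusted p = 0.121). Of 46 interferon-response genes 7 rose and 1 fell, or 13 and 1 adjusted over the list alone, with the antiviral gene Ifit3 at 2.99 ± 0.48 (adjusted p = 0.000102). Of 73 ribosomal protein genes 29 fell and 0 rose, or 54 and 0 adjusted over the list alone. Saa2, an acute-phase protein made mainly by the liver, rose by 8.08 ± 1.39 (adjusted p = 0.000230). It rose by 5.28 ± 0.80 with the hepatocyte mean as a covariate, by 9.09 ± 2.06 with scan day as a block (adjusted p = 0.0259) and by 8.69 ± 2.54 with slides 5 to 8 as a block (adjusted p = 0.0448). Rab17, a small GTPase of epithelial cells, rose by 4.50 ± 0.61 (adjusted p = 9.24e-06), but by 0.85 ± 0.88 with slides 5 to 8, which hold all arrays of this group, as a block (adjusted p = 0.626). Of 10 genes named for this dose, 9 lay beyond every sham array in 6 of 6 exposed arrays.

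At acute 2.2 Gy the list medians were 0.46 for p53 targets, -1.55 for B-cell, -1.09 for erythroid, 1.02 for platelet, 0.46 for interferon and -0.78 for ribosomal protein genes. The adjusted p from camera were 1.58e-06, 8.76e-17, 4.05e-06, 1.47e-12, 2.66e-06 and 3.72e-20. With an estimated correlation the values in that order were adjusted p = 0.148, 0.148, 0.478, 0.256, 0.270 and 0.170. Once scan day was blocked, the medians were 0.46, -1.95, -0.91, 1.35, 0.44 and -0.95, and with the hepatocyte covariate 0.66, -1.18, -0.86, 1.26, 0.82 and -0.64. With slides 5 to 8 as a block the p53, interferon and erythroid medians were 0.57, 0.35 and 0.24, and these 3 calls ended (adjusted p = 0.114, 0.392 and 0.440). Of 1704 genes that passed, 673 were higher and 1031 lower, but the balance turned with quantile normalization (925 and 713), the series table values (965 and 669) and the hepatocyte covariate (946 and 656). Without acute sham replicate 6 the count was 1073, with scan day as a block 147 (when Nusap1 and Gp1bb had adjusted p of 0.131 and 0.133), and with normexp background correction 192.

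**Figure D2:**
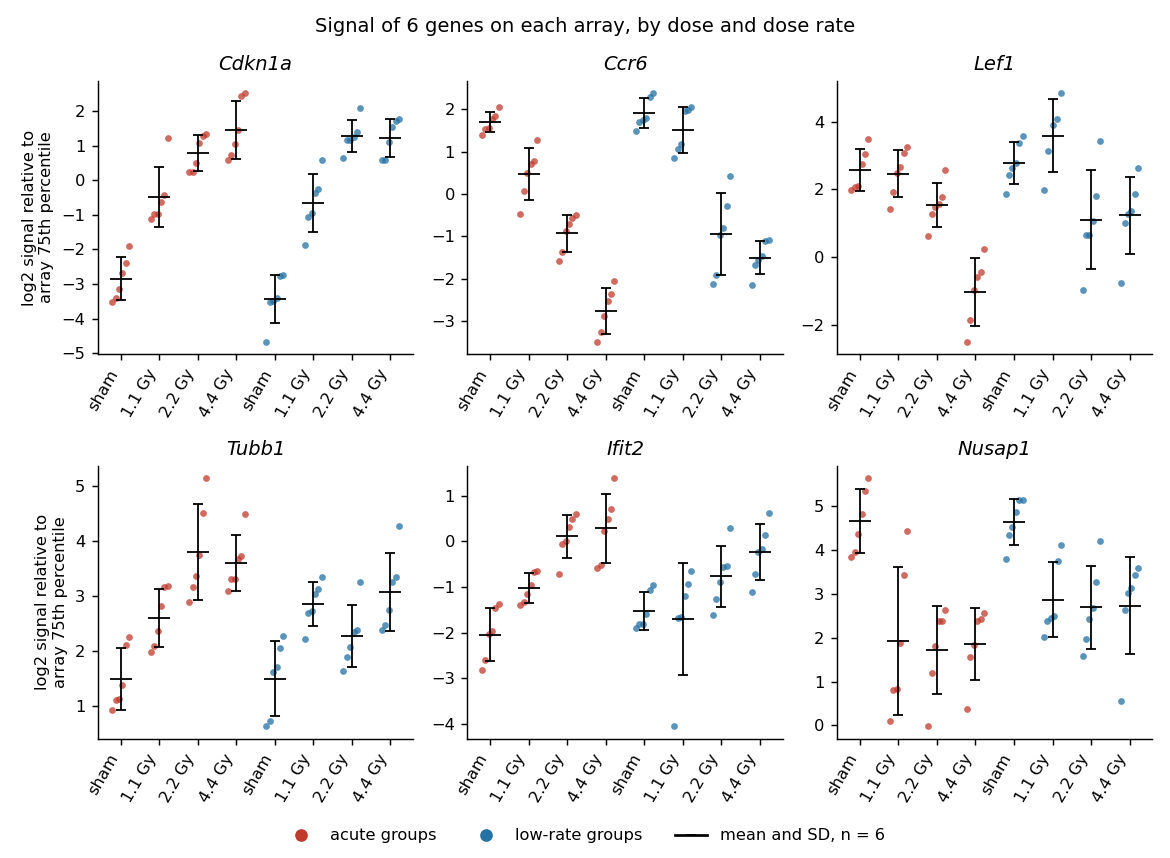
Log2 signal relative to the 75th percentile of the array (y axis) of Cdkn1a, Ccr6, Lef1, Tubb1, Ifit2 and Nusap1 against dose in Gy (x axis) for both rates. Points are arrays and bars the mean with its SD, with 6 arrays per group; mean Cdkn1a went from -2.84 in acute sham to 1.47 at acute 4.4 Gy, and from -3.43 to 1.23 at the low rate.

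In the main fit acute 4.4 Gy gave the most called genes of the 6 comparisons with sham, 2776, with 1293 higher and 1483 lower. Some other settings ranked another group first. The balance turned with quantile normalization (1493 and 1131), the series table values (1795 and 804), scan day as a block (334 and 329) and the hepatocyte covariate (1155 and 711). Cdkn1a rose by 4.31 ± 0.40 (log2, SE, 6 against 6 arrays, adjusted p = 5.35e-10) and Aen by 2.44 ± 0.28 (adjusted p = 9.32e-08). The Cdkn1a probe lies on chromosome 17 at 29237377 to 29237436 of build mm9. Of 42 p53 targets 13 rose and 2 fell, or 16 and 2 adjusted over the list alone. Of 28 B-cell genes 22 fell and 0 rose, or 24 and 0 adjusted over the list alone. Vpreb3, which associates with the pre-B-cell receptor, changed by -4.92 ± 0.46 (adjusted p = 5.72e-10). Ccr6, a chemokine receptor carried by B cells and some T cells, changed by -4.46 ± 0.33 (adjusted p = 3.54e-13). Its probe lies on chromosome 17 at 8449933 to 8449992. Of 11 genes of antigen presentation by MHC class II 9 fell and 0 rose, or 10 and 0 adjusted over the list alone.

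Of 32 T-cell genes at acute 4.4 Gy 21 fell and 1 rose, or 23 and 1 adjusted over the list alone. Lef1, a transcription factor of naive T cells, changed by -3.60 ± 0.54 (adjusted p = 1.51e-05), and Dapl1, outside the lists, by -5.55 ± 0.53 (adjusted p = 6.76e-10). Of 26 platelet genes 12 rose and 0 fell, or 22 and 0 adjusted over the list alone, with Tubb1 at 2.10 ± 0.36 (adjusted p = 0.000104). Of 40 erythroid genes 14 fell and 2 rose, or 22 and 4 adjusted over the list alone. Of 41 proliferation genes 10 fell and 0 rose, or 14 and 0 adjusted over the list alone, with the replication licensing factor Cdt1 at -2.26 ± 0.42 (adjusted p = 0.000400). Of 46 interferon-response genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone, with Ifit2 at 2.34 ± 0.39 (adjusted p = 9.88e-05). The receptor Cx3cr1, carried by patrolling monocytes, changed by -2.63 ± 0.55 (adjusted p = 0.00141). Saa2 rose by 8.53 ± 1.39 (adjusted p = 6.32e-05), by 5.53 ± 0.81 with the hepatocyte covariate, by 9.55 ± 2.06 with scan day as a block (adjusted p = 0.00773) and by 9.14 ± 2.54 with slides 5 to 8 as a block (adjusted p = 0.0306). All 11 genes, picked on these same arrays, lay beyond every one of the 6 sham arrays in 6 of 6 exposed arrays.

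The list medians at acute 4.4 Gy were 0.66 for p53 targets, -2.02 for B-cell, -2.03 for T-cell, -1.80 for MHC class II, 1.10 for platelet, -1.06 for erythroid, -0.80 for proliferation and 0.34 for interferon genes. Camera gave adjusted p of 9.95e-08, 7.66e-21, 6.02e-15, 2.41e-10, 2.37e-13, 3.09e-05, 0.000137 and 0.000860. With an estimated correlation the values were adjusted p = 0.0616, 0.0616, 0.126, 0.126, 0.248, 0.432, 0.252 and 0.399. With scan day as a block the medians were 0.56, -2.42, -2.37, -2.16, 1.53, -0.89, -0.57 and 0.38, and with the hepatocyte covariate 0.69, -1.63, -1.49, -1.36, 1.40, -0.83, -0.42 and 0.66. With slides 5 to 8 as a block the erythroid, proliferation and interferon medians were 0.27, 0.13 and 0.13, and these 3 calls ended (adjusted p = 0.456, 0.480 and 0.681). With the signal level as a covariate the erythroid and interferon medians were -0.37 and 0.14, and their calls ended (adjusted p = 0.182 and 0.268). When scan day was a block, 663 genes passed, and Cdt1 had an adjusted p of 0.146; with slides 5 to 8 as a block it was at -1.04 ± 0.74 (adjusted p = 0.481). With normexp background correction 568 genes passed.

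**Figure D3:**
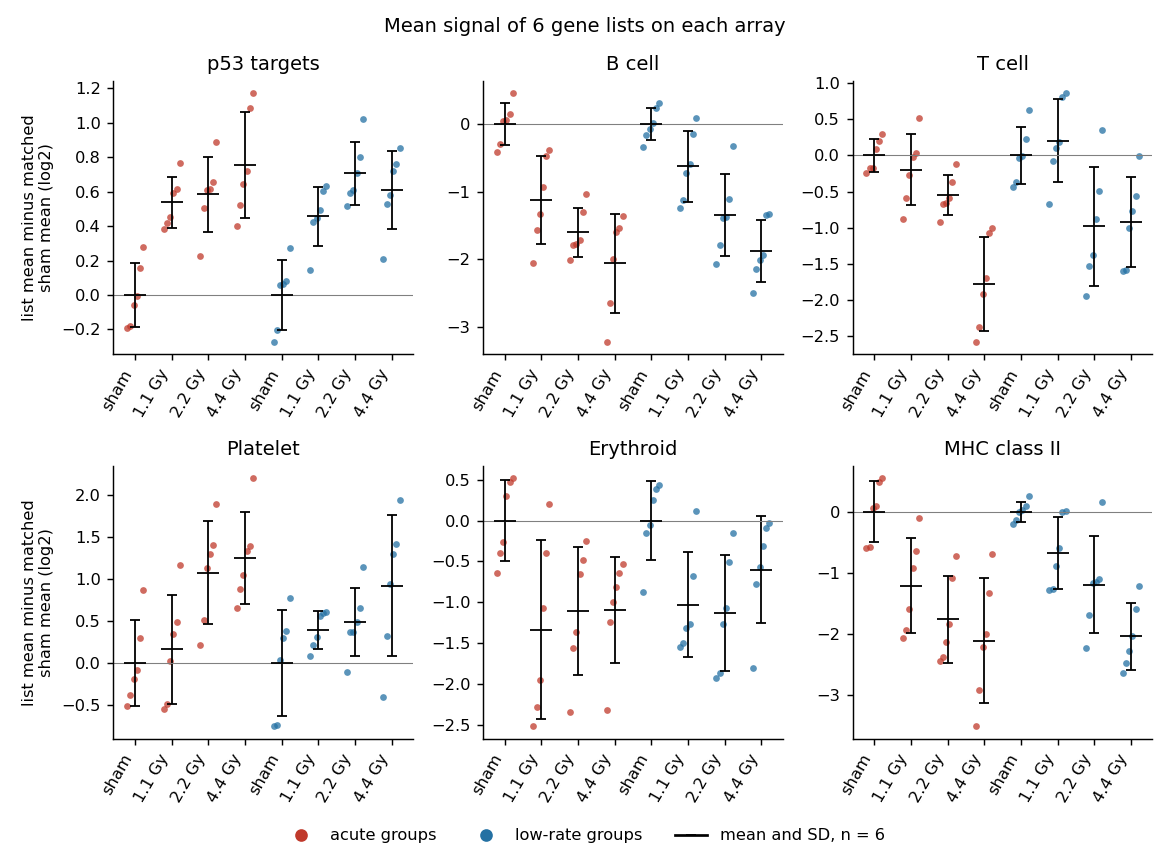
Change of the list mean from the matched sham mean (y axis, log2) against dose in Gy (x axis) for p53 targets, B-cell, T-cell, platelet, erythroid and MHC class II genes at both rates. Points are arrays and bars the mean with its SD, with 6 arrays per group. With slides 5 to 8 as a block, which rests on acute 1.1 Gy, the erythroid change at acute 2.2 and 4.4 Gy turned positive.

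The low-rate groups ask for the same changes when the dose was spread over hours. At low-rate 1.1 Gy Cdkn1a rose by 2.79 ± 0.40 (log2, SE, 6 against 6 arrays, adjusted p = 0.000244) and Aen by 1.40 ± 0.28 (adjusted p = 0.0155). Of 42 p53 targets 5 rose and 0 fell, or 11 and 1 adjusted over the list alone. Of 28 B-cell genes 0 passed, also adjusted over the list alone, and their median was -0.65. Of 40 erythroid genes 2 fell, or 18 adjusted over the list alone. The largest rise among the named genes was that of Amy2a5, the pancreatic amylase, at 7.38 ± 1.49 (adjusted p = 0.0155). The mean of 22 pancreatic acinar genes was higher in this group by 2.42 (exact permutation p = 0.0368, adjusted p = 0.132). Dmbt1, a mucosal glycoprotein, was at least 5.28-fold higher (adjusted p = 0.0144), since 0 of 6 sham arrays were well above background. With normexp background correction it was higher by 1.66 (log2, adjusted p = 0.103), below that bound. Of these 4 genes 3 lay beyond every sham array in 6 of 6 exposed arrays.

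The p53, B-cell and erythroid medians at low-rate 1.1 Gy were 0.34, -0.65 and -0.99. The adjusted p from camera were 1.79e-05, 0.00141 and 1.11e-06, and adjusted p = 0.317, 0.700 and 0.700 with an estimated correlation. With the hepatocyte mean as a covariate the B-cell median was -0.36 and its call ended (adjusted p = 0.0782). Blocked by scan day, the medians were 0.38, -0.88 and -0.97, and within scan day 1 (2 exposed and 3 sham arrays) 0.67, -0.91 and -1.86. Of 190 genes that passed, 93 were higher and 97 lower, but 31 and 8 with scan day as a block and 26 and 18 with the hepatocyte covariate. The count was 6, 71, 81, 57 and 99 without sham replicates 3, 1, 4, 5 and 6, and 56, 472, 122 and 32 without exposed replicates 1, 2, 3 and 6. Without sham replicate 3 the calls of Aen (adjusted p = 0.0514) and Amy2a5 (adjusted p = 0.0603) ended, and without exposed replicate 6 that of Amy2a5 (adjusted p = 0.0513). Under a block for scan day, 39 genes passed, and Aen and Amy2a5 had adjusted p of 0.107 and 0.151. The call of Amy2a5 also ended within scan day 1 (adjusted p = 0.126) and under a fixed block for slide (adjusted p = 0.113), which passed 256 genes.

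At low-rate 2.2 Gy p53 targets rose and B-cell genes fell. Cdkn1a was higher by 4.72 ± 0.40 (log2, SE, 6 against 6 arrays, adjusted p = 5.21e-11) and the cyclin Ccng1 by 1.97 ± 0.33 (adjusted p = 0.000566). Of 42 p53 targets 10 rose and 0 fell, or 15 and 0 adjusted over the list alone. Of 28 B-cell genes 9 fell and 0 rose, or 20 and 0 adjusted over the list alone. Vpreb3 changed by -2.94 ± 0.46 (adjusted p = 0.000254), the IgE receptor Fcer2a by -2.15 ± 0.32 (adjusted p = 0.000104) and Ccr6 by -2.85 ± 0.33 (adjusted p = 3.76e-07). Of 32 T-cell genes 0 passed, and 16 were lower and 0 higher adjusted over the list alone. Of 40 erythroid genes 8 fell and 0 rose, or 20 and 0 adjusted over the list alone. A fixed block for slide left 1 gene passing, with Vpreb3 at -1.37 (adjusted p = 1), Fcer2a at -1.62 (0.385), Ccr6 at -2.03 (0.385) and Ccng1 at 1.97 (0.402). Within scan day 2 their adjusted p were 0.676, 0.253, 0.210 and 0.210.

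Low-rate 2.2 Gy also had more macrophage transcripts. The scavenger receptor Marco was higher by 4.13 ± 0.96 (adjusted p = 0.0152) and the complement component C1qc by 4.04 ± 0.88 (adjusted p = 0.00997). The protease inhibitor Slpi was higher by 2.37 ± 0.49 (adjusted p = 0.00601). Of the 22 macrophage genes 16 rose and 0 fell, with a median of 3.54, which was 3.41 with scan day as a block and 3.60 and 3.35 within days 1 and 2. All 8 genes named for low-rate 2.2 Gy lay beyond every sham array in 6 of 6 exposed arrays. Without low-rate sham replicate 6 the calls of Marco (adjusted p = 0.0797) and C1qc (0.0659) ended. The calls of Marco, C1qc and Slpi also ended within day 1 (adjusted p = 0.0722, 0.0585 and 0.189), within day 2 (0.621, 0.428 and 0.176) and under a fixed block for slide (1, 0.976 and 0.388), with values of 3.30, 3.46 and 2.80 in the last.

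The medians at low-rate 2.2 Gy were 0.58 for p53 targets, -1.12 for B-cell, -1.06 for T-cell and -1.13 for erythroid genes. Camera gave adjusted p of 7.21e-11, 4.82e-21, 3.54e-11 and 3.54e-11, and adjusted p = 0.00844, 0.0395, 0.173 and 0.303 with an estimated correlation. With scan day as a block the medians were 0.62, -1.13, -1.01 and -1.19. Within day 1 (4 exposed and 3 sham arrays) they were 0.53, -1.69, -1.39 and -0.97, and within day 2 (2 and 3 arrays) 0.46, -0.41, -0.50 and -1.66, where the T-cell call ended (adjusted p = 0.153). It ended also under a fixed block for slide (adjusted p = 0.240), where the medians were 0.44, -0.31, -0.44 and -1.69. Of 361 genes that passed, 190 were higher and 171 lower, but the balance turned in 11 other settings, among them normexp background correction (44 and 177) and quantile normalization (131 and 143). The count was 166 and 191 without exposed replicates 4 and 1, and 234 and 80 without sham replicates 5 and 6. Within day 2 only 1 gene passed.

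At low-rate 4.4 Gy some lymphocyte genes were lower and some p53 targets higher, though with an estimated correlation the T-cell and p53 list calls ended (adjusted p = 0.249 and 0.121). Cdkn1a rose by 4.66 ± 0.40 (log2, SE, 6 against 6 arrays, adjusted p = 8.02e-11) and Psrc1, a p53 target that acts on microtubules, by 2.60 ± 0.37 (adjusted p = 1.23e-05). Of 42 p53 targets 12 rose and 1 fell, or 13 and 3 adjusted over the list alone. Of 28 B-cell genes 21 fell and 0 rose, with the same counts adjusted over the list alone. Vpreb3 changed by -3.98 ± 0.46 (adjusted p = 2.89e-07). Of 11 MHC class II genes 8 fell and 0 rose, or 11 and 0 adjusted over the list alone, with H2-Ob at -3.60 ± 0.56 (adjusted p = 5.52e-05). Of 32 T-cell genes 8 fell and 0 rose, or 14 and 0 adjusted over the list alone. Among them were the transcription factor Tcf7 at -2.07 ± 0.49 (adjusted p = 0.0109) and the interleukin-7 receptor Il7r at -2.44 ± 0.55 (adjusted p = 0.00724).

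Of 26 platelet genes at low-rate 4.4 Gy 3 rose and 0 fell, or 9 and 0 adjusted over the list alone. The platelet integrin Itga2b was higher by 2.35 ± 0.48 (adjusted p = 0.00266) and Tubb1 by 1.57 ± 0.36 (adjusted p = 0.00786). Cdt1 changed by -1.86 ± 0.42 (adjusted p = 0.00786). Of 40 erythroid genes 4 fell and 2 rose, or 9 and 2 adjusted over the list alone. Of 73 ribosomal protein genes 13 fell and 0 rose, or 37 and 0 adjusted over the list alone. Under a fixed block for slide 33 genes passed. The calls that ended there were those of Itga2b (1.23, adjusted p = 0.740), Tubb1 (1.27, 0.732), Cdt1 (-1.78, 0.693), Psrc1 (2.59, 0.0656), H2-Ob (-3.30, 0.103), Tcf7 (-2.55, 0.452) and Il7r (-2.63, 0.484), and the erythroid list (adjusted p = 0.494). Of 9 genes named for low-rate 4.4 Gy, 7 lay beyond every sham array in 6 of 6 exposed arrays.

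The medians at low-rate 4.4 Gy were 0.36 for p53 targets, -2.00 for B-cell, -1.0 for T-cell, -1.82 for MHC class II, 0.80 for platelet, -0.65 for erythroid and -0.64 for ribosomal protein genes. The adjusted p from camera were 9.84e-06, 1.33e-30, 6.34e-09, 1.96e-16, 4.05e-09, 0.00455 and 8.58e-20. With an estimated correlation the values were adjusted p = 0.121, 0.0203, 0.249, 0.0420, 0.284, 0.793 and 0.167. Within scan day 2 (6 exposed and 3 sham arrays) the medians were 0.49, -1.83, -0.97, -1.71, 0.78, -0.38 and -0.61, and with scan day as a block 0.40, -2.03, -1.13, -2.01, 0.79, -0.46 and -0.55. Of 1029 genes that passed, 294 were higher and 735 lower. The count was 666, 408 and 621 without sham replicates 2, 1 and 6, and 365 and 420 without exposed replicates 4 and 5. Within day 2 it was 148, and Tcf7, Il7r, Tubb1 and Cdt1 had adjusted p of 0.0609, 0.0790, 0.0834 and 0.102 there, and the erythroid call ended (adjusted p = 0.0944).

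The dose-rate comparisons ask whether the change at a dose differed between the rates, as the low-rate change minus the acute change. For Cdkn1a the difference was 0.41 ± 0.56, 1.09 ± 0.56 and 0.35 ± 0.56 (log2, SE) at 1.1, 2.2 and 4.4 Gy, with adjusted p of 0.998, 0.957 and 0.802. At 1.1 Gy 0 genes passed in limma, with 866 at an unadjusted p under 0.05. At 4.4 Gy 0 genes passed, with 1944 at an unadjusted p under 0.05. There Lef1 differed by 2.06 ± 0.76 (adjusted p = 0.356). The T-cell list differed by a median of 0.94 at 4.4 Gy (camera adjusted p = 0.000233, and adjusted p = 0.745 with an estimated correlation), with 0 of 32 members passing. The 18 heat-shock genes differed by -1.09, with 0 passing, or 5 lower adjusted over the list alone (camera adjusted p = 7.05e-10, and adjusted p = 0.125 with an estimated correlation). Taking scan day as a block, these medians were 1.29 and -1.53, and with slides 5 to 8 as a block 1.37 and -1.42. The T-cell call ended with normexp background correction (0.30, adjusted p = 0.390) and with dim probes kept (0.94, adjusted p = 0.206). The 4.4 Gy count was 5, 12 and 5 without low-rate sham replicates 3 and 4 and low-rate 4.4 Gy replicate 6. It was 7, 3, 2 and 4 without acute sham replicates 1, 4, 5 and 6, and 1 without acute 4.4 Gy replicate 2.

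At 2.2 Gy 14 genes differed between the rates, 0 higher and 14 lower at the low rate, with 1085 at an unadjusted p under 0.05. The sperm protamine Prm2 differed by -4.86 ± 0.84 (adjusted p = 0.00785) and Rab17 by -4.64 ± 0.86 (adjusted p = 0.0127). These genes were high on slides 5 to 8, which hold all arrays of acute 2.2 and 4.4 Gy and 4 of acute 1.1 Gy, and no sham or low-rate array. With these slides as a block the differences were -1.71 ± 1.06 (adjusted p = 0.377) for Prm2 and -0.99 ± 1.01 (adjusted p = 0.595) for Rab17, and 22 genes passed, 13 higher and 9 lower. With scan day as a block 0 genes passed. The platelet list differed by a median of -0.63 (camera adjusted p = 1.28e-05, and adjusted p = 0.880 with an estimated correlation) and the ribosomal protein list by 0.60 (camera adjusted p = 2.03e-18, and adjusted p = 0.660 with an estimated correlation), with 0 members of either passing. When scan day was a block, they differed by -0.90 and 0.76, with slides 5 to 8 as a block by -1.71 and 0.78, and with normexp background correction the ribosomal median was -0.25. At 1.1 Gy the B-cell list differed by 0.49 (camera adjusted p = 0.000235, and adjusted p = 0.899 with an estimated correlation), and by 0.50 with scan day as a block, 0.80 with slide as a fixed block and 0.97 with slides 5 to 8 as a block, which passed 138 genes at 1.1 Gy. That call ended with normexp background correction (0.099, adjusted p = 0.682), with array weights (0.25, adjusted p = 0.393) and without 5 noisy arrays (0.30, adjusted p = 0.181). The 2.2 Gy count was 8 without low-rate 2.2 Gy replicate 5, 25 and 9 without low-rate sham replicates 2 and 5, and 6 without acute sham replicate 1 or acute 2.2 Gy replicate 6.

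**Figure D4:**
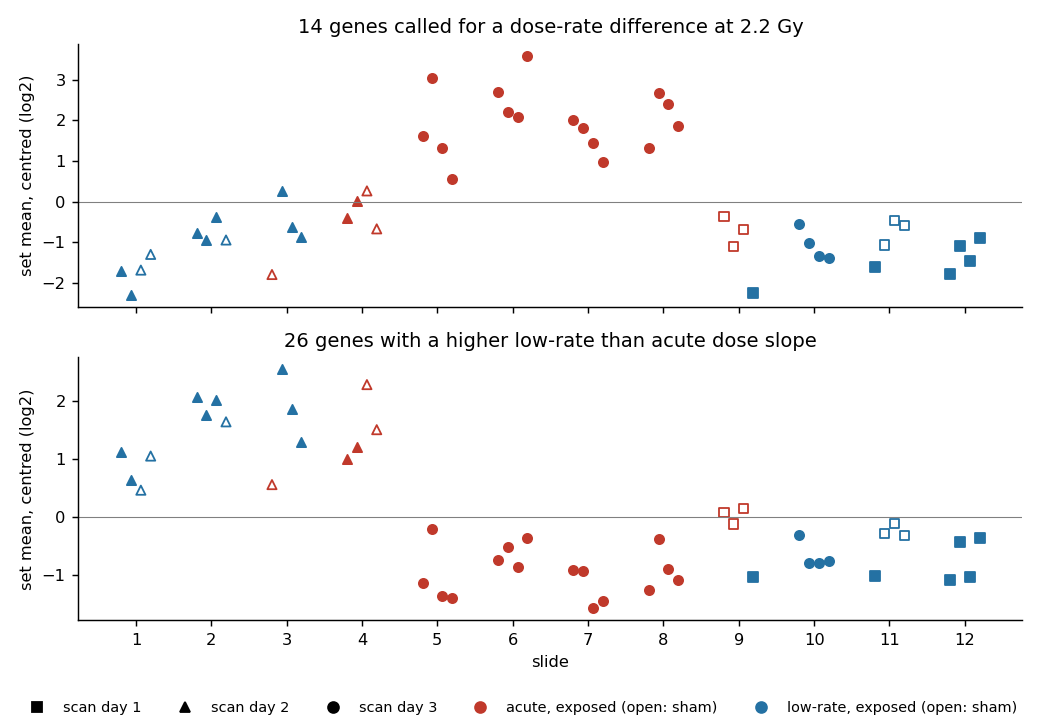
Mean log2 signal (y axis, relative to the mean of all arrays) of the 14 genes that differed between the rates at 2.2 Gy and of 26 of the genes whose dose slope differed, per array by slide (x axis), with the scan day marked. The 14-gene mean ran from 0.560 to 3.59 on slides 5 to 8 and from -2.30 to 0.266 on the others.

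The changes at the same dose were also compared gene by gene. At 1.1 Gy 4 genes were higher at both rates (0.160 by chance) and 24 lower (0.792). Both groups have 4 arrays on scan day 3, which holds no sham array, so a batch may add to this overlap. At 2.2 Gy 56 were higher (6.10 by chance) and 134 lower (8.41) at both. At 4.4 Gy 184 were higher (18.1) and 410 lower (52) at both, and 3 of the genes lower in the acute arm were higher at the low rate. Of the genes that passed at either rate, 337 of 369 at 1.1 Gy, 1692 of 1875 at 2.2 Gy and 2827 of 3208 at 4.4 Gy had the same sign in both. The correlation between the rates across genes was 0.662, 0.610 and 0.466, and genes are not independent replicates.

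Comparing low-rate sham with acute sham asks whether the procedures differed in effect without radiation, since the sham mice of each rate were treated like its exposed mice. In limma 0 genes passed, with 502 at an unadjusted p under 0.05. The count was 1 without acute sham replicate 1 or 3, and 16 within scan day 2 (3 against 3 arrays).

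Dose slopes ask which genes had a straight-line trend over the stated doses. Whether a gene changed evenly from dose to dose was not tested. In the acute arm Cdkn1a rose by 0.92 ± 0.09 (log2 per Gy, SE, 24 arrays, adjusted p = 5.28e-10), Ccr6 changed by -1.01 ± 0.07 (adjusted p = 6.43e-14) and Lef1 by -0.86 ± 0.12 (adjusted p = 2.31e-06). At the low rate Cdkn1a rose by 1.00 ± 0.09 (adjusted p = 7.25e-11), Ccr6 changed by -0.84 ± 0.07 (adjusted p = 5.09e-11) and Itga2b rose by 0.53 ± 0.10 (adjusted p = 0.00170). In the acute arm 22 of 28 B-cell and 22 of 32 T-cell genes had a falling slope, and 12 of 42 p53 targets and 19 of 26 platelet genes a rising one. At the low rate these counts were 21, 13, 12 and 3. Adjusted over the list alone they were 24, 24, 14 and 21 in the acute arm and 21, 20, 13 and 4 at the low rate. Slopes of the other sign were found for 1 p53 target at each rate and for 1 T-cell gene in the acute arm.

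The median slopes in the acute arm were -0.41 for B-cell, -0.47 for T-cell, 0.14 for p53 and 0.29 for platelet genes. Camera gave adjusted p of 9.81e-21, 1.09e-17, 4.36e-07 and 7.05e-17, and adjusted p = 0.0790, 0.0973, 0.0790 and 0.140 with an estimated correlation. At the low rate they were -0.43, -0.27, 0.08 and 0.19, with adjusted p of 7.51e-33, 6.07e-14, 0.000130 and 4.65e-08, and adjusted p = 0.0137, 0.167, 0.167 and 0.318 with an estimated correlation. Blocked by scan day, the medians were -0.49, -0.52, 0.13 and 0.38 in the acute arm and -0.42, -0.25, 0.09 and 0.16 at the low rate. A slope passed for 2580 genes in the acute arm (1294 rising and 1286 falling, but 1187 and 2068 without the filter on dim probes and 1685 and 660 with the series table values) and for 1015 at the low rate (379 and 636). Without acute 4.4 Gy replicate 3 the acute count was 1692. The low-rate count was 360, 417, 484 and 622 without low-rate 4.4 Gy replicates 4 and 5 and low-rate sham replicates 1 and 6. With scan day as a block the counts were 752 and 418. Under a fixed block for slide the low-rate count was 38, the slope of Itga2b 0.26 ± 0.17 (adjusted p = 0.380) and the p53 call ended (adjusted p = 0.129).

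The slope differed between the rates for 27 genes, 26 higher and 1 lower at the low rate, with 2100 at an unadjusted p under 0.05. L1cam, a neural adhesion molecule, differed by 1.37 ± 0.30 log2 per Gy (adjusted p = 0.0386) and Rab17 by -0.90 ± 0.19 (adjusted p = 0.0316). Once scan day was blocked, and likewise with slides 5 to 8 as a block, 0 genes passed, and with the signal level as a covariate 3 were higher and 5 lower. Taking scan day as a block, L1cam differed by 0.24 ± 0.18 (adjusted p = 0.901) and Rab17 by -0.20 ± 0.18 (adjusted p = 0.901). Leaving out any of 20 arrays moved the count by over 1.5 times. It was 11, 66, 1, 7 and 1 without low-rate sham replicates 2, 4, 1, 5 and 6, 13 without low-rate 1.1 Gy replicate 1, and 11, 3, 1, 16 and 81 without low-rate 4.4 Gy replicates 1, 3, 4, 5 and 6. It was 43, 9, 5 and 43 without acute sham replicates 1, 2, 3 and 5, 57 without acute 1.1 Gy replicate 5, and 9, 7, 1 and 12 without acute 4.4 Gy replicates 1, 3, 5 and 6. The call of L1cam ended without 14 of these arrays, with adjusted p from 0.0511 to 0.105, and that of Rab17 without 9, with adjusted p from 0.0563 to 0.0774.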

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

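All tests on the 3 patterns weighed here, and all splits of the arrays, were chosen after the results had been seen.

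Liver transcripts were present in many arrays, sham arrays included. The 30 hepatocyte genes moved together within groups, with a median pairwise correlation of 0.943 between their deviations from the group mean, as RNA of liver cells entering the samples in varying amounts would give; liver lies along the path of a cardiac puncture, and no value here tests that route. Irradiation as the whole cause is argued against by the 12 sham arrays, whose hepatocyte mean ranged over 10.4 log2 units against a largest exposed-minus-sham difference of 3.28. Liver RNA went with most of the acute-phase rise at acute 4.4 Gy. Whether it was the whole cause cannot be told, as the acute-phase list was written after the arrays were seen. The 15-gene mean, higher by 4.29 (log2), was higher by 1.43 ± 0.29 (SE) with the hepatocyte mean as a covariate. With scan day or slides 5 to 8 as a block the rise was 4.84 ± 1.78 or 4.29 ± 2.20, and with those slides and the covariate 1.10 ± 0.51. Neither batch alone shrank the rise, but the SE is too wide to exclude one. A radiation effect may remain or not.

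The genes that differ between the dose rates follow slides and scan days. The 14 genes found at 2.2 Gy were higher by 1.82 (log2) on slide 5 than on slide 4 within acute 1.1 Gy. This compared 4 and 2 arrays and is what a batch shared by slides 5 to 8 would give. Slide 4 had the most variation between repeated probes (25.8% to 34.9%). Its 14-gene mean was yet the highest outside slides 5 to 8 (-0.20), so it did not lie low. The 26 genes with a higher slope at the low rate were higher by 1.44 on scan day 2 than on day 1 within the 3 groups scanned on both (exact permutation p = 0.000167 of 6000 arrangements), as a scan day 2 batch would give. Dose rate itself cannot be told apart from slide for the 14 genes, since slides 5 to 8 hold 0 sham or low-rate arrays; for the 26 genes it is argued against as the whole cause, since the slope difference of their mean, 0.82 (log2 per Gy), fell by 0.45 ± 0.07 (SE) with scan day as a block. A batch is therefore a candidate explanation for the 14 genes and for part of the slope difference of the 26, while the remaining 0.37 ± 0.10 was measured on genes picked for this difference and stays open.

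Macrophage transcripts were higher at low-rate 2.2 Gy and at acute 2.2 and 4.4 Gy. Scan day is argued against at low-rate 2.2 Gy, where the mean of the 22 genes was still higher by 2.99 ± 0.70 (log2, SE) with scan day as a block, and the median by 3.41. Exposure as the cause cannot be told, since the list was written after these genes had been seen at low-rate 2.2 Gy, and at low-rate 4.4 Gy the mean was higher by 1.67 with an exact permutation p of 0.0758. The macrophage and hepatocyte means had r = 0.191 within groups, but Spearman rho = -0.0094, and r = -0.010 without the farthest arrays. These values give no sign of a source shared with the liver transcripts but do not exclude one. Whether such RNA came from blood cells or from tissue may differ between groups and was not tested.

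Splits of the same arrays into groups of the same sizes were tested, 100 per comparison with the real one included. They showed how often as many genes are called when any array may change places with any other. In each of the 13 comparisons, the smallest share these splits can give is 1 in 100. They exchange arrays between slides and scan days and so do not exclude a batch: with scan day as a block acute 2.2 and 4.4 Gy had 147 and 663 genes, and the rate difference at 2.2 Gy and the slope difference 0. For acute 1.1 Gy 11 of 100 splits gave at least the real 207 genes and the highest other gave 5049, so chance cannot be excluded. For acute 2.2 and 4.4 Gy 1 split each, the real one, gave as many genes, so chance is unlikely. The real counts were 1704 and 2776 and the highest others 162 and 1873. The same holds for low-rate 1.1 Gy (1 split, 190 genes, highest other 5) and low-rate 4.4 Gy (1 split, 1029 genes, 305). For low-rate 2.2 Gy 2 splits gave as many as the real 361 and the highest other gave 890, so chance is unlikely but not excluded. For the rate differences at 1.1 and 4.4 Gy and for the sham groups the real count was 0, which all 100 splits must reach, so the splits decide nothing there; the highest others gave 1623, 1222 and 1. For the rate difference at 2.2 Gy 2 splits gave as many as the real 14 and the highest other gave 1363. The low-rate slope had 1 split with as many, the real one (1015 genes, highest other 172), so chance is unlikely there too. The acute slope had 2 splits with as many, the highest other reaching the same 2580 as the real one. The slope difference also had 2 splits with as many (27 genes, highest other 1846). For the acute slope, the slope difference and the rate difference at 2.2 Gy chance is therefore unlikely but not excluded. Of the 13 highest other splits 5 had the largest contrast in array signal level of the 99 others, and 2 had the largest contrast in the hepatocyte mean.

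Some samples stood far from the other 5 of their group. This was tested in 225 groups of values and found in 16 of them, or 7.11%, where chance gives about 1 in 20. Among genes, Cdkn1a in acute 1.1 Gy replicate 2 was 1.22 (log2) and Rab17 in acute sham replicate 1 was -3.53. Dmbt1 in low-rate sham replicate 4 was -3.77 and C1qc in low-rate sham replicate 6 was -3.98. Among list means, acute sham replicate 1 stood apart for interferon (1.63), heat-shock (2.27) and macrophage genes (-1.96). The pancreatic acinar mean was 0.25 in acute 4.4 Gy replicate 4 and 0.17 in low-rate 2.2 Gy replicate 1. The share of spots well above background was 39.9% in low-rate sham replicate 4 and 35.8% in low-rate 4.4 Gy replicate 1. The scanner software marked 414 outlier spots in acute 2.2 Gy replicate 3, 318 in low-rate sham replicate 4 and 2119 in low-rate 1.1 Gy replicate 3. The variation between repeated probes was 15.0% in acute 2.2 Gy replicate 2, and the 75th percentile of the signal was 365 in acute sham replicate 1.

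Some effects differed between the rates by a test of the difference itself. These were the 14 genes at 2.2 Gy, among them Prm2 (-4.86) and Rab17 (-4.64), and the 27 genes whose slope differed, among them L1cam (1.37 per Gy) and Rab17 (-0.90 per Gy). By camera's preset correlation, but not with an estimated one, they were also the B-cell list at 1.1 Gy (0.49), the platelet (-0.63) and ribosomal protein (0.60) lists at 2.2 Gy, and the T-cell (0.94) and heat-shock (-1.09) lists at 4.4 Gy.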

How the results depend on the processing

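The settings with scan day or slides 5 to 8 as a block, within a scan day, without 5 noisy arrays, and with the hepatocyte mean or the signal level as a covariate were chosen after the results had been seen.

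Most named genes and list medians kept their direction and their side of the threshold when the signal was processed otherwise, but most gene calls ended within scan day 2 and with slide as a fixed block. Of 60 gene values 59 did so with quantile normalization, with outlier spots kept, with replicate number as a block and with array weights. All 60 did so without the filter on dim probes, with every probe tested and with a trended robust fit. With normexp background correction 44 of 60 did, with slide as a random block 54 and with slide as a fixed block 9 of 29. Within scan day 1 it was 8 of 12 gene values and 7 of 7 list medians, and within scan day 2 6 of 21 and 11 of 14. With scan day as a block 48 of 60 gene values did, with slides 5 to 8 as a block 50, without 5 noisy arrays 57, with the hepatocyte covariate 56 and with the signal level covariate 59. Of 44 list calls 44 held with scan day as a block and 43 with the hepatocyte covariate, 37 with slides 5 to 8 as a block and 18 of 22 with slide as a fixed block, but 5 held when camera estimated the correlation. Signal over background limits what can be seen: the median SE of a log2 change was 0.44, and at 2-fold 11 of 100 simulated genes were recovered for acute 4.4 Gy.

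The counts of called genes moved more. Those given here are over 1.5 times higher or lower than reported, and the cause was not tested. Quantile normalization gave 427 for acute 1.1 Gy, 3 for the rate difference at 4.4 Gy and 8 for the slope difference. Normexp background correction gave 10, 192 and 568 for acute 1.1, 2.2 and 4.4 Gy. For low-rate 1.1, 2.2 and 4.4 Gy it gave 1.1e+02 (23 higher and 84 lower), 221 and 238. The acute and low-rate slopes had 749 and 161, and the rate difference at 2.2 Gy and the slope difference 0. Without the filter on dim probes the counts were 105 for acute 1.1 Gy, 80 for low-rate 1.1 Gy, 648 for low-rate 4.4 Gy and 614 for the low-rate slope. With probes above background on all 48 arrays the counts were 318 for acute 1.1 Gy, 1467 for acute 4.4 Gy, 151 for low-rate 2.2 Gy, 577 for low-rate 4.4 Gy, 2 for the rate difference at 2.2 Gy, 1284 for the acute slope, 499 for the low-rate slope and 1 for the slope difference. The series table values gave 1, 29 and 4 for the rate differences at 1.1, 2.2 and 4.4 Gy and 9 for the slope difference. With every probe tested it was 327 for acute 1.1 Gy. Fitting the arrays of the compared groups alone gave 0 for acute 1.1 Gy, 1523 for acute 4.4 Gy, 606 for low-rate 2.2 Gy, 30 for the rate difference at 2.2 Gy and 5 for the rate difference at 4.4 Gy. With slide as a random block the counts were 15, 540 and 1021 for acute 1.1, 2.2 and 4.4 Gy. At the same low-rate doses they were 72, 149 and 268. They were 4 for the rate difference at 2.2 Gy, 781 and 255 for the acute and low-rate slopes and 0 for the slope difference. With slide as a fixed block they were 60 for acute 1.1 Gy, 1 for low-rate 2.2 Gy, 33 for low-rate 4.4 Gy, 3 for the rate difference at 1.1 Gy and 38 for the low-rate slope. With replicate number as a block they were 113 for low-rate 1.1 Gy and 16 for the slope difference. Array weights gave 13179, 5927 and 6955 for acute 1.1, 2.2 and 4.4 Gy. At the low rate they gave 6199, 5308 and 3954. The rate differences at these doses had 1821, 614 and 335, and the sham groups 9. The acute slope had 4228, the low-rate slope 3877 and the slope difference 98. The weights ran from 0.155 to 24.6. Pooling the 12 sham arrays gave 851 and 3114 for acute 1.1 and 2.2 Gy. For low-rate 1.1, 2.2 and 4.4 Gy it gave 2574, 1115 and 1960. Comparing the rates without the sham groups gave 283, 681 and 340 for the rate differences at 1.1, 2.2 and 4.4 Gy. With scan day as a block the counts were 36 for acute 1.1 Gy, 147 for acute 2.2 Gy, 663 for acute 4.4 Gy, 39 for low-rate 1.1 Gy, 676 for low-rate 4.4 Gy, 0 for the rate difference at 2.2 Gy, 752 for the acute slope, 418 for the low-rate slope and 0 for the slope difference. Within scan day 1 they were 59 and 89 for low-rate 1.1 and 2.2 Gy. Within scan day 2 they were 1 for low-rate 2.2 Gy, 148 for low-rate 4.4 Gy and 16 for the sham groups. With slides 5 to 8 as a block they were 404 for acute 1.1 Gy, 745 for acute 2.2 Gy, 922 for acute 4.4 Gy, 327 for low-rate 1.1 Gy, 138 for the rate difference at 1.1 Gy, 22 for the rate difference at 2.2 Gy, 943 for the acute slope and 0 for the slope difference. Without 5 noisy arrays they were 668 for acute 1.1 Gy and 363 and 1815 for low-rate 1.1 and 4.4 Gy. They were 1866 and 0 for the low-rate slope and the slope difference, and 7, 46 and 2 for the rate differences by rising dose. With the hepatocyte covariate they were 18 for acute 1.1 Gy, 44 for low-rate 1.1 Gy, 31 for the rate difference at 2.2 Gy, 1 for the rate difference at 4.4 Gy, 1564 for the low-rate slope and 14 for the slope difference. With the signal level as a covariate they were 464 for acute 1.1 Gy, 3337 for acute 2.2 Gy, 1343 for low-rate 1.1 Gy, 1849 for low-rate 4.4 Gy, 84 for the rate difference at 2.2 Gy, 9 for the rate difference at 4.4 Gy, 1681 for the low-rate slope and 8 for the slope difference. With groups by tag they were 3 at low-rate 1.1 and 2.2 Gy and 2 for the rate difference at 2.2 Gy. The other comparisons with sham and the slopes gave 0.

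Leaving out 1 array at a time gave 13 to 812, 1073 to 2186 and 1938 to 3846 for acute 1.1, 2.2 and 4.4 Gy. At the low rate it gave 6 to 472, 80 to 507 and 365 to 1437. The rate differences at 1.1, 2.2 and 4.4 Gy had 0 to 0, 6 to 25 and 0 to 12. The sham groups had 0 to 1. The acute slope had 1692 to 3154, the low-rate slope 360 to 1354 and the slope difference 1 to 81.

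The balance of higher and lower genes, given in that order, turned in some settings. For acute 1.1 Gy (36 and 171) it turned with the hepatocyte covariate (13 and 5). For acute 2.2 Gy (673 and 1031) it turned with quantile normalization (925 and 713), the series table values (965 and 669) and the hepatocyte covariate (946 and 656). For acute 4.4 Gy (1293 and 1483) it turned with quantile normalization (1493 and 1131), the series table values (1795 and 804), scan day as a block (334 and 329) and the hepatocyte covariate (1155 and 711). For low-rate 1.1 Gy (93 and 97) it turned with groups by treatment tag (3 and 0), dim probes kept (42 and 38), outlier spots kept (90 and 83), the series table values (113 and 85), the compared groups alone (115 and 78), scan day as a block (31 and 8) and the hepatocyte covariate (26 and 18). For low-rate 2.2 Gy (190 and 171) it turned with quantile normalization (131 and 143), normexp background correction (44 and 177), dim probes kept (129 and 135), probes above background on all 48 arrays (68 and 83), the series table values (146 and 156), every probe tested (221 and 234), slide as a random block (67 and 82), slides 5 to 8 as a block (197 and 206), without 5 noisy arrays (242 and 279), the signal level covariate (245 and 293) and scan day 1 alone (31 and 58). For the rate difference at 2.2 Gy (0 and 14) it turned with groups by treatment tag (2 and 0) and slides 5 to 8 as a block (13 and 9). For the acute slope (1294 and 1286) it turned with dim probes kept (1187 and 2068), slide as a random block (365 and 416), replicate number as a block (1224 and 1230), array weights (2045 and 2183), slides 5 to 8 as a block (426 and 517), without 5 noisy arrays (1047 and 1307) and the signal level covariate (1769 and 1991). For the slope difference (26 and 1) it turned with the signal level covariate (3 and 5).

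Calls (genes, or lists by median) that ended without a turn follow, each with its log2 value and adjusted p, for the settings other than a fixed block, a single scan day and an estimated correlation. Grouping by treatment tag ended Cdkn1a (0.049, 1.00) for acute 1.1 Gy, Ifit3 (0.063, 1.00) for acute 2.2 Gy, Aen (0.041, 0.999), Tubb1 (0.30, 0.999), Cdt1 (-0.57, 0.999), Cx3cr1 (-0.12, 0.999), Saa2 (0.29, 0.999), B-cell genes (-0.10, 0.649), T-cell genes (-0.098, 0.797), MHC class II genes (-0.085, 0.649), erythroid genes (-0.087, 0.517), platelet genes (0.032, 0.797) and proliferation genes (-0.15, 0.0891) for acute 4.4 Gy, Amy2a5 (4.90, 1.00) and Dmbt1 (2.67, 1.00) for low-rate 1.1 Gy, Ccng1 (0.047, 0.993), Marco (0.30, 0.982) and C1qc (0.22, 0.986) for low-rate 2.2 Gy, Il7r (-0.25, 0.913) for low-rate 4.4 Gy, Rab17 (-0.46, 0.999) for the rate difference at 2.2 Gy, T-cell genes (0.28, 0.628) for the rate difference at 4.4 Gy, B-cell genes (-0.033, 0.255) for the acute slope, Itga2b (0.015, 0.978) and T-cell genes (-0.027, 0.740) for the low-rate slope, L1cam (0.83, 0.855) and Rab17 (-0.45, 0.855) for the slope difference. Quantile normalization ended L1cam (1.36, 0.0534) for the slope difference. Normexp background correction ended Cdkn1a (0.58, 0.606), Aen (1.00, 0.381) and Cd79a (-1.47, 0.0884) for acute 1.1 Gy, Fcrl1 (-0.91, 0.325) and Gp1bb (1.74, 0.0504) for acute 2.2 Gy, Aen (0.77, 0.299) and Dmbt1 (1.66, 0.103) for low-rate 1.1 Gy, Fcer2a (-0.81, 0.115), Slpi (1.78, 0.197) and Marco (3.09, 0.05004) for low-rate 2.2 Gy, Psrc1 (1.05, 0.146) and Tubb1 (1.38, 0.109) for low-rate 4.4 Gy, B-cell genes (0.099, 0.682) for the rate difference at 1.1 Gy, Prm2 (-3.85, 0.0653) and Rab17 (-2.75, 0.186) for the rate difference at 2.2 Gy, T-cell genes (0.30, 0.390) for the rate difference at 4.4 Gy, L1cam (1.08, 0.222) and Rab17 (-0.56, 0.222) for the slope difference. Keeping dim probes ended T-cell genes (0.94, 0.206) for the rate difference at 4.4 Gy. Restriction to probes above background on all 48 arrays ended interferon genes (0.36, 0.0777) for acute 4.4 Gy, B-cell genes (-0.62, 0.114) for low-rate 1.1 Gy, erythroid genes (-0.54, 0.331) for low-rate 4.4 Gy. Keeping outlier spots ended Cd79a (-1.73, 0.102) for acute 1.1 Gy. The series table values ended L1cam (1.30, 0.0847) for the slope difference. Fitting the compared groups alone ended Cdkn1a (2.37, 0.372), Aen (1.56, 0.372), Cd79a (-1.73, 0.372) and Nusap1 (-2.74, 0.372) for acute 1.1 Gy. Slide as a random block ended Cd79a (-1.80, 0.0983) and Nusap1 (-2.41, 0.116) for acute 1.1 Gy, Marco (3.96, 0.0594) for low-rate 2.2 Gy, Tubb1 (1.44, 0.0534) for low-rate 4.4 Gy, L1cam (1.25, 0.232) and Rab17 (-0.83, 0.232) for the slope difference. Replicate number as a block ended L1cam (1.37, 0.0571) for the slope difference. Array weights ended B-cell genes (0.25, 0.393) for the rate difference at 1.1 Gy, L1cam (1.11, 0.0571) for the slope difference. Leaving out 5 noisy arrays ended Cd79a (-1.51, 0.0784) for acute 1.1 Gy, B-cell genes (0.30, 0.181) for the rate difference at 1.1 Gy, L1cam (1.01, 0.201) and Rab17 (-0.84, 0.0742) for the slope difference. The hepatocyte covariate ended Cd79a (-1.42, 0.133) and Nusap1 (-2.32, 0.116) for acute 1.1 Gy, B-cell genes (-0.36, 0.0782) for low-rate 1.1 Gy, L1cam (1.30, 0.0624) and Rab17 (-0.87, 0.0531) for the slope difference. The signal level covariate ended erythroid genes (-0.37, 0.182) and interferon genes (0.14, 0.268) for acute 4.4 Gy, L1cam (1.21, 0.134) for the slope difference.

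Some directions turned, and the cause was not tested. With normexp background correction the ribosomal protein median of the rate difference at 2.2 Gy was -0.25. With probes above background on all 48 arrays the p53 median at acute 1.1 Gy was -0.0091. With slides 5 to 8 as a block the erythroid medians at acute 2.2 and 4.4 Gy were 0.24 and 0.27, and the proliferation median at acute 4.4 Gy was 0.13. Grouping by treatment tag, which mixes the groups used here in another row order, turned 39 of 60 gene values and 32 of 44 list medians. Acute 1.1 Gy gave Aen -0.22, Cd79a 0.45 and Nusap1 0.41, with medians of -0.18 (p53), 0.23 (B-cell) and 0.12 (erythroid). Acute 2.2 Gy gave Cdkn1a -0.81, Phlda3 -0.50, Fcrl1 0.88, Fcmr 0.13, Nusap1 0.52, Tubb1 -0.40, Gp1bb -0.58, Saa2 -1.89 and Rab17 -0.082, with medians of -0.15 (p53), 0.19 (B-cell), 0.015 (erythroid), -0.39 (platelet), -0.054 (interferon) and 0.035 (ribosomal protein). Acute 4.4 Gy gave Cdkn1a -0.25, Vpreb3 0.28, Ccr6 0.094, Dapl1 0.23, Lef1 0.30 and Ifit2 -0.40, with medians of -0.14 (p53) and -0.32 (interferon). Low-rate 1.1 Gy gave Cdkn1a -1.32 and Aen -0.72, with medians of -0.32 (p53), 0.74 (B-cell) and 0.21 (erythroid). Low-rate 2.2 Gy gave Cdkn1a -0.12, Vpreb3 0.37, Ccr6 0.51, Fcer2a 0.22 and Slpi -0.040, with medians of -0.097 (p53), 0.41 (B-cell) and 0.028 (T-cell). Low-rate 4.4 Gy gave Cdkn1a -1.52, Psrc1 -0.42, Vpreb3 0.86, H2-Ob 0.039, Tcf7 0.10, Itga2b -0.12, Tubb1 -0.32 and Cdt1 0.056, with medians of -0.45 (p53), 0.27 (B-cell), 0.19 (T-cell), 0.24 (MHC class II), 0.57 (erythroid), -0.21 (platelet) and 0.041 (ribosomal protein). The rate difference at 2.2 Gy gave Prm2 0.37, with medians of 0.065 (platelet) and -0.27 (ribosomal protein). The acute slope gave Cdkn1a -0.083, Ccr6 0.013 and Lef1 0.090, with medians of -0.0075 (p53), 0.0008 (T-cell) and -0.0037 (platelet). The low-rate slope gave Cdkn1a -0.26 and Ccr6 0.074, with medians of -0.086 (p53), 0.025 (B-cell) and -0.028 (platelet).

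Some settings gave no value. The treatment tags form 1 sham group, so the sham groups could not be compared. With slide as a fixed block acute 2.2 and 4.4 Gy, their rate differences, the acute slope and the slope difference could not be estimated. Within a scan day acute 2.2 and 4.4 Gy and the rate differences could not be estimated, and no slope was fitted. Pooling the sham arrays applies to the comparisons with sham alone, and the filter on all 48 arrays left 22 of the 60 gene values.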

Other observations

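The lists of other tissues were written after the arrays had been examined, and the correlations and the tests on these lists were chosen after the results had been seen.

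Beyond the groups already described, low-rate 1.1 Gy stood out for pancreatic transcripts. Of 22 pancreatic acinar genes 7 rose and 0 fell, with a median of 1.91 (log2), which was 1.99 with scan day as a block and 1.74 within scan day 1. The mean exceeded the highest sham array in 5 of 6 exposed arrays. In the other comparisons with sham the median lay between -0.45 and 0.28. Mast cell genes had a median of 1.41 at low-rate 2.2 Gy (8 genes measured, exact permutation p = 0.0152, adjusted p = 0.0779) and cardiac muscle genes 0.54 at low-rate 4.4 Gy (11 genes, exact permutation p = 0.0152, adjusted p = 0.0779).

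Genes of inflammation, B cells and T cells moved against the liver transcripts within groups, while plasma-cell genes moved with them. Over the 48 arrays, the deviation of the hepatocyte mean from its group mean was related to that of 32 other list means. For genes of inflammation r was -0.749 (Spearman rho = -0.815, permutation p = 1e-05 for both, the smallest they can give, adjusted p = 4e-05 and 3.56e-05), and -0.769 without the 2 farthest arrays. Within scan days 1, 2 and 3 it was -0.707, -0.879 and -0.680. For B-cell genes r was -0.584 (rho = -0.593, permutation p = 4e-05 and 5e-05, adjusted p = 0.000128 and 0.000133), -0.603 without 2 arrays, and -0.677, -0.456 and -0.687 within days. For T-cell genes r was -0.589 (rho = -0.561, permutation p = 5e-05 and 0.00019, adjusted p = 0.000145 and 0.00038), -0.574 without 2 arrays, and -0.633, -0.580 and -0.550 within days. For plasma-cell genes r was 0.405 (rho = 0.447, permutation p = 0.00278 and 0.00148, adjusted p = 0.00445 and 0.00263), 0.422 without 2 arrays, and -0.111, 0.460 and 0.551 within days. For platelet and erythroid genes r was -0.322 and -0.339 (adjusted p = 0.0598 and 0.0507) and rho -0.359 and -0.350 (adjusted p = 0.0344 and 0.0346). For circadian genes r was 0.751 (rho = 0.761, permutation p = 1e-05 for both, adjusted p = 4e-05 and 3.56e-05), 0.740 without 2 arrays, and 0.756, 0.673 and 0.894 within days. For p53 targets r was -0.158 (rho = -0.121, permutation p = 0.297 and 0.446, adjusted p = 0.328 and 0.510), -0.136 without 2 arrays, and 0.286, -0.316 and -0.166 within days. The first component of the within-group deviations held 35% of their variance, and its scores had r = 0.720 with the hepatocyte mean.

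Liver RNA may dilute the blood transcripts of an array, and part of the fall in B-cell and T-cell genes could then follow the hepatocyte mean. With that mean as a covariate the B-cell medians at acute 1.1, 2.2 and 4.4 Gy were -0.86, -1.18 and -1.63, against -1.23, -1.55 and -2.02 without it, so that at these doses most of the change stayed. At low-rate 2.2 and 4.4 Gy they were -1.0 and -1.89, against -1.12 and -2.00. At low-rate 1.1 Gy the median was -0.36 with the covariate, against -0.65, and the call ended (camera adjusted p = 0.0782). The covariate differs between the groups, so this does not separate its effect from that of exposure.

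The labels give a replicate number within each group, and it did not pair arrays of different groups. Deviations of arrays with the same number had a median correlation of -0.010 across genes, against -0.0068 for different numbers, and 5 of 48 arrays were closest to one with their own number.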
